A study of Homo sapiens with 16 samples.

How the data were processed

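Total RNA of HepG2 cells, a human hepatocellular carcinoma line, was measured on 16 single-colour expression arrays after biotin labelling, per the labels' protocols. The arrays fall into 4 groups of 4, named here as in the labels. Groups ASO_3+4, ASO_5+6 and ASO_7+8 each received a pair of antisense oligonucleotides (ASOs) against ZFAS1, and CTLASO received a control oligonucleotide. Each group was sampled at passages 12, 13, 19 and 20, and the replicate number used here is the passage. Cells were exposed for 48 h to 30 nM of oligonucleotide in total, which was 15 nM of each member of a pair.

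The values in the deposited table are log2 signals, 1 per summarised probe set and array, and the authors made them in Affymetrix Expression Console, per the submitters' processing notes. The normalization algorithm and the software version are not given in the sources used here. The table holds 24351 rows, of which 2903 are control rows and 21448 are not. The platform table pairs 17709 of the latter with 1 gene symbol each, none with several, and leaves 3739 unnamed here. All 17709 Entrez identifiers were found in the RefSeq gene table of GRCh38.p14, and 0 symbols needed updating. No coordinates are printed, because no genome build was given for the array. Where a gene had several probe sets (20 genes), the one with the highest mean was kept, which left 17687 genes.

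ZFAS1 and the small nucleolar RNAs of its introns are not named in the platform table, so the level of the targeted transcript was not analysed here. The groups are therefore taken from the labels alone, and the knockdown is unchecked.

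Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 16 arrays, with 12 residual degrees of freedom, no block and 1 estimate of the spread per gene for all groups. Each comparison was adjusted by Benjamini-Hochberg over the 17687 genes, at a threshold of 0.05. A change is a difference of group means on the log2 scale with its standard error (SE). All comparisons with CTLASO share the same 4 control arrays, so 100 simulated sets of unchanged groups were compared with them. Before the data were examined, 30 gene lists were fixed, covering the ZFAS1 neighbourhood, liver functions, lipid metabolism, cell cycle, stress and signalling responses, ribosomes, mitochondria and markers of other cell types. They held 743 genes, of which 619 were measured, and the 29 lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. Camera sets a list against all other genes. Fry asks whether a list's genes move, on balance, one way.

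Named genes follow a rule fixed before the data were examined. For each ASO pair against CTLASO it takes the 8 largest rises and 8 largest falls that passed the threshold, had 1 sign at all 4 passages and lay at or above the 40th percentile of mean signal (5.51 log2). It adds ZNFX1, up to 4 members of each list by smallest p, up to 10 genes changed alike by all 3 pairs, and the 5 largest differences between each 2 pairs of ASOs. Where fewer than 5 genes passed, the 5 with the smallest p are given as not passing. Genes outside the rule are said to be chosen after their values were seen.

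The labels tie arrays of different groups through the passage they share. Of 24 same-passage pairs of arrays from different groups, 12 had deviations from their group means that correlated above 0.1 across genes and 5 correlated below -0.1 (range -0.55 to 0.39, median 0.12). Between ASO_3+4 and CTLASO these correlations were negative at every passage, at -0.18, -0.55, -0.44 and -0.24 for passages 12, 13, 19 and 20. A fit with passage as a block was run as an alternative, and a common block cannot take up such opposite moves. Nothing in the labels says whether the 4 passages of a group were independent cultures, so p-values measure the spread between these arrays.

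The procedure was tested on simulated data with the real means and spreads of ASO_3+4 against CTLASO over 17687 genes. Of genes shifted by 0.5 log2 it recovered 5.97%, of those shifted by 1 log2 52.2%, and of those shifted by 2 log2 100%, with 12 false calls. The number of arrays limits the precision.

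Alternatives set before the data were examined were the passage block, quantile normalization, centring on array medians, removal of dim genes, the mean of a gene's probe sets, eBayes with trend and robust options, a fit of only the groups compared, early or late passages alone, a change of at least 1.5-fold, other list tests, and leaving out each array in turn. Array weights, inclusion of unnamed rows, passages 12 and 13 and passages 19 and 20 as separate groups in 1 fit, and, for comparisons that do not hold ASO_3+4, counts without its array of passage 12 were added after seeing the data, as was leaving out each ASO array for the genes that rose with both ASO_3+4 and ASO_7+8. Figures were drawn with matplotlib 3.10.9.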

Results

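Expression was measured in HepG2 cells treated for 48 h with 1 of 3 pairs of antisense oligonucleotides against ZFAS1, a long noncoding RNA transcribed antisense to the 5' end of ZNFX1, or with a control oligonucleotide. Per the design text, ASO_3+4 and ASO_5+6 target exons of 1 transcript model and ASO_7+8 those of another. Each group had 4 arrays, at passages 12, 13, 19 and 20. Median gene signal per array ranged from 6.44 to 6.57 log2, the median of negative control rows from 4.18 to 4.45 and that of background control rows from 5.41 to 5.47. The first principal component held 32.4% of the variance and the second 19.6%. The ASO_3+4 array of passage 12 had the lowest spread over genes (SD 3.00 log2). Correlations between arrays of 1 group went as low as 0.976 in ASO_3+4 and 0.978 in CTLASO, against 0.992 in ASO_5+6. The ASO_3+4 arrays of passages 19 and 20 correlated at 0.989 to 0.990 with the controls of passages 12 and 13. With the ASO_3+4 array of passage 12 they correlated at only 0.976 and 0.979, and with that of passage 13 at 0.984 and 0.987. Early and late controls correlated at 0.978 to 0.982.

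**Figure D1:**
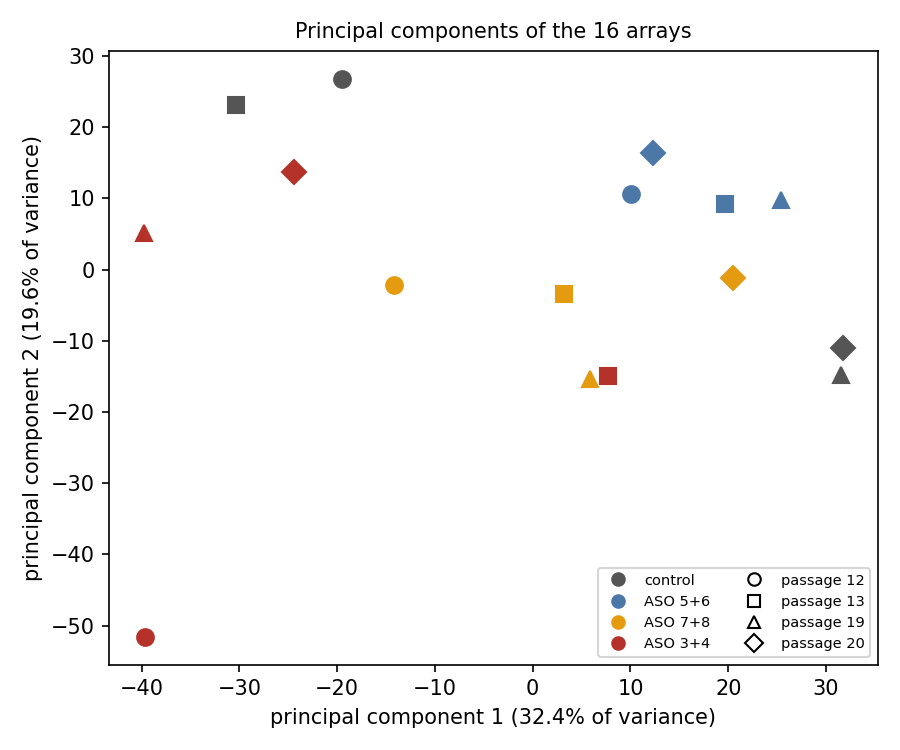
Position of each of the 16 arrays on the first (32.4% of variance) and second (19.6%) principal components of log2 signal, with colour for group and marker shape for passage. The control arrays of passages 12 and 13 lie at -19.5 and -30.4 on the first component, and those of passages 19 and 20 at 31.6 and 31.7.

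The first comparison asked which genes changed with ASO_3+4 against the control oligonucleotide. The largest fall was LRMDA, a gene for melanocyte differentiation, which fell by 2.51 log2 (SE 0.23, adjusted p = 1.78e-05, n = 4 per group, limma), from 8.65 ± 0.38 in CTLASO to 6.14 ± 0.33 (SD). CUL4A, a ubiquitin ligase scaffold, fell by 2.41 (SE 0.29), RALY, an RNA-binding protein, by 2.16 (SE 0.21), and MYH9, a nonmuscle myosin heavy chain, by 1.83 (SE 0.33). PSKH1, BTBD2, PTPRG and IMMP2L fell by 1.82, 1.80, 1.80 and 1.78. The largest rise was TNNC1, a troponin subunit, at 2.48 log2 (SE 0.28, adjusted p = 1.02e-04), from 8.60 ± 0.11 to 11.08 ± 0.38. GLIPR1 rose by 2.09, SFN, the cell cycle inhibitor 14-3-3 sigma, by 1.87, GPAT3, a glycerolipid synthesis enzyme, by 1.80, and MMP3, a matrix protease, by 1.77. CYP24A1, which inactivates vitamin D, rose by 1.74, BCL2A1, an inhibitor of apoptosis, by 1.68, and RCL1 by 1.64. MMP3 in control (5.51) and IMMP2L with ASO_3+4 (5.44) lay near the medians of the background control rows, so the sizes of these 2 changes are uncertain. In total 198 of 17687 genes changed, 101 up and 97 down (83 and 119 with arrays centred, 109 and 81 with quantile normalization). Of the 198, 192 had 1 sign at all 4 passages, which their choice by the mean change over these passages favours. ZNFX1, the neighbour of ZFAS1, was 0.52 log2 below control (SE 0.24, adjusted p = 0.370) and did not pass.

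The control arrays of this comparison differed by passage. In a fit with passages 12 and 13 apart from passages 19 and 20, added after seeing the data, ASO_3+4 changed 870 genes at the earlier passages and 1651 at the later. Of the 284 genes called in both, 51 had the same sign and 233 the opposite sign. Without the ASO_3+4 array of passage 12 the count was 123, of which 116 were among the 198, and without the control array of passage 19 it was 113. Without the ASO_3+4 array of passage 13 it was 321. In the fit of the compared groups alone 34 genes passed. The main fit also takes its spread from ASO_5+6 and ASO_7+8. Estimated array weights, lower for noisier arrays, were 0.35 to 1.23 in ASO_3+4 and 0.62 to 1.10 in control. They were 1.32 to 1.82 in ASO_5+6 and 0.85 to 1.34 in ASO_7+8. Of 32 genes named here as passing, 24 passed without any 1 of the 8 arrays, and BTBD2, IGFBP1, ACLY, MCM6, TAGLN, POLR1A, CD68 and SERPINE2 did not. These genes also lost their call in the fit of the compared groups alone. So did CDKN1A, GADD45A, AKR1B10, GCLM, MYH9, PSKH1, PTPRG, CYP24A1 and KRT19.

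Cell cycle genes lay below control with ASO_3+4. All 30 measured G2/M genes had negative values (mean -0.68 log2), none passed over all genes, and 23 were lower when adjusted over the list alone. The list had an adjusted camera p of 6.87e-18 and an adjusted p = 0.108 with an estimated correlation. Its per-passage differences from control were -0.89, -0.07, -1.02 and -0.75 at passages 12, 13, 19 and 20. DLGAP5, NUF2 and NDC80, which act at the mitotic spindle or kinetochore, had values of -1.23, -1.19 and -1.34. Among 29 G1/S genes (mean -0.53; adjusted camera p = 1.26e-11, adjusted p = 0.128 with an estimated correlation), 1 passed, and 9 were lower when adjusted over the list alone. At passages 19 and 20 alone the G1/S mean was -0.30 and the list was not called (adjusted p = 0.0782). The gene that passed was MCM6, a replicative helicase subunit, which fell by 0.94. POLA1 and GINS1 had values of -0.94 and -1.17 and did not pass.

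Of 25 p53 target genes, 2 rose with ASO_3+4. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 1.15 (SE 0.20, adjusted p = 0.00484) and GADD45A by 1.13, while the list as a whole was not called. Among 23 NRF2 and oxidative stress genes (mean 0.34; adjusted camera p = 7.56e-04, adjusted p = 0.130 with an estimated correlation), 3 rose and 5 were higher when adjusted over the list alone. At passages 12 and 13 alone the mean was 0.15 and the list was not called (adjusted p = 0.400). The 3 that rose were SRXN1, which repairs peroxiredoxins (1.52), AKR1B10, an aldo-keto reductase (1.33), and GCLM, a subunit of glutathione synthesis (1.13). AKR1B10 was also the 1 gene that passed among 24 bile acid and xenobiotic genes (mean 0.28; adjusted p = 0.00494 and, with an estimated correlation, adjusted p = 0.130). Without the ASO_3+4 array of passage 12 the bile acid and xenobiotic call was lost (adjusted p = 0.0548), as it was at the early (adjusted p = 0.115) or late passages alone (adjusted p = 0.0849). G6PC1 and IGFBP1, of the glucose list, rose by 1.36 and 1.56, and that list was not called. The control level of G6PC1, 4.38 log2, lay within the range of the negative control medians, so the size of its rise is uncertain.

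Further lists were called with ASO_3+4. Among 23 mesenchymal and matrix genes (mean 0.34; adjusted camera p = 7.56e-04, adjusted p = 0.0549 with an estimated correlation), TAGLN, an actin-binding protein, rose by 1.24, and CCN2 had a value of 0.87 that did not pass. The 36 interferon-stimulated genes had a mean of 0.31 (adjusted p = 0.00254; with an estimated correlation adjusted p = 0.128), and none passed. IFI27 lay at 6.55 log2 with ASO_3+4 and 5.17 in control, where it was below the background control medians, and SAMD9 lay at 4.61 log2 with ASO_3+4 and 3.60 in control, where it was below the negative control medians, so their differences are not given. Of 11 leukocyte markers (mean 0.29; adjusted p = 0.0159; with an estimated correlation adjusted p = 0.128) 1 rose, CD68, a lysosomal glycoprotein, by 1.15. The leukocyte call was lost without the ASO_3+4 array of passage 12 (adjusted p = 0.0915) and without the control array of passage 19 (adjusted p = 0.0567), and at the early (adjusted p = 0.158) or late passages alone (adjusted p = 0.329). Cholesterol synthesis (mean -0.29 over 20 genes), fatty acid oxidation (-0.22 over 25) and ribosome biogenesis (-0.20 over 28) were called down at adjusted camera p of 0.00790, 0.00790 and 0.0243. With an estimated correlation they had adjusted p of 0.261, 0.261 and 0.209. Fry called none of these 3 (adjusted p = 0.128, 0.128 and 0.0781), and ribosome biogenesis was also lost with quantile normalization, bright genes only and array weights (adjusted p = 0.173, 0.103 and 0.0616). Without the ASO_3+4 array of passage 12 the 3 means were -0.16, -0.084 and -0.11, and none was called (adjusted p = 0.160, 0.171 and 0.171). Fatty acid oxidation and ribosome biogenesis were not called without the control array of passage 12 either (adjusted p = 0.125 and 0.0812), nor ribosome biogenesis without that of passage 13 (adjusted p = 0.131). At passages 19 and 20 alone fatty acid oxidation and ribosome biogenesis lay above control, at 0.075 and 0.032, and cholesterol synthesis (-0.15, adjusted p = 0.507), interferon-stimulated (0.18, adjusted p = 0.353) and mesenchymal genes (0.19, adjusted p = 0.353) were not called. The differences of fatty acid oxidation from control by passage were -0.86, -0.18, -0.03 and 0.18. POLR1A, the largest subunit of RNA polymerase I, fell by 0.82. Single members also passed in lists that were not called. NKD1, a Wnt antagonist, fell by 1.61, and ACLY, which makes cytosolic acetyl-CoA, by 1.02, while LGR5 had a value of -1.16 that did not pass. None of the 10 called lists held with an estimated correlation.

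**Figure D2:**
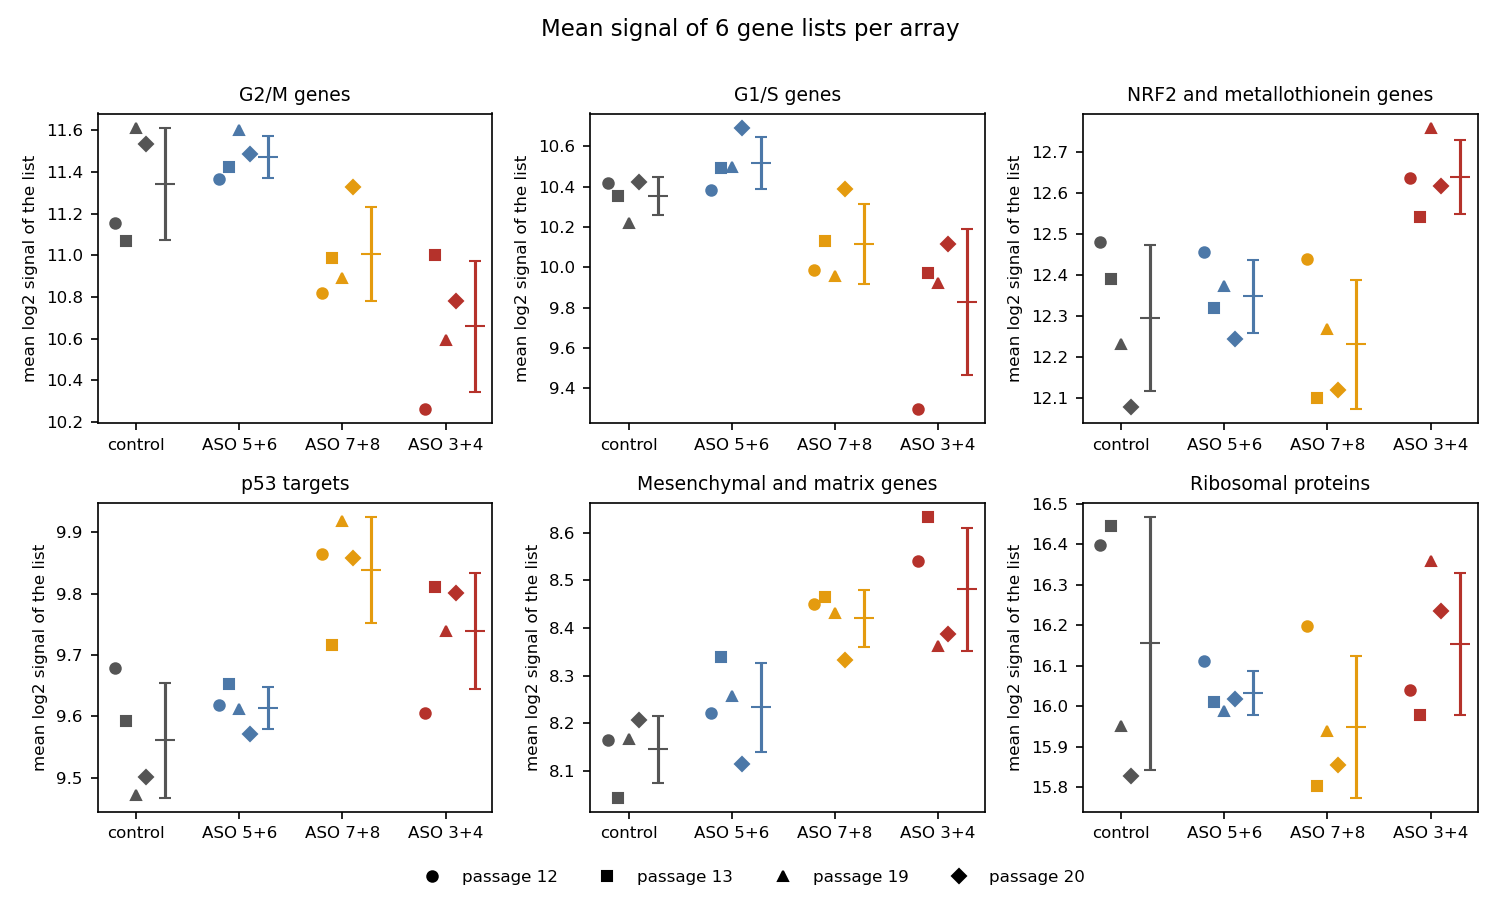
Mean log2 signal of 6 gene lists in each array, by group, with marker shape for passage and bars for the mean ± SD of 4 arrays. The G2/M mean was 10.66 ± 0.31 with ASO_3+4 and 11.34 ± 0.27 in control.

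The same question was asked of ASO_5+6, and no gene passed. The 5 smallest p-values belonged to MLF2 (1.55 log2, SE 0.28), TRUB2, a pseudouridine synthase (1.35), RAD9A, a DNA damage checkpoint protein (1.07), FLT3 and USF3 (-0.94), with adjusted p from 0.282 to 0.449 in limma. FLT3 lay at 3.23 log2 with ASO_5+6 and 4.39 in control, within or below the range of the negative control medians in both groups. At an unadjusted p under 0.05 there were 723 genes, against 884.35 by chance, and the passage block also called 0. ZNFX1 was 0.43 above control (SE 0.24, adjusted p = 0.997). The 20 cholesterol synthesis genes had a mean of 0.21 (adjusted camera p = 0.0153; with an estimated correlation adjusted p = 0.554), with EBP at 0.43 and MSMO1 at 0.71. The 28 ATF4 genes had a mean of 0.18 (adjusted p = 0.0153; with an estimated correlation adjusted p = 0.554), with the serine synthesis enzymes PSPH and PSAT1 at 0.76 and 0.55. Hypoxia and glycolysis genes had a mean of 0.16 (adjusted p = 0.0355; with an estimated correlation adjusted p = 0.759). Ribosomal protein genes had a mean of -0.12 (adjusted p = 0.0153; with an estimated correlation adjusted p = 0.787). No member of these 4 lists passed, and fry called 0 lists. Cholesterol synthesis, ATF4 and hypoxia and glycolysis genes lost their camera call with quantile normalization (adjusted p = 0.0598, 0.0598 and 0.0632). The same held with bright genes only (adjusted p = 0.122, 0.106 and 0.243). Array weights also ended the hypoxia and glycolysis call (adjusted p = 0.119). All 4 lists lost their call without the ASO_5+6 array of passage 19 (adjusted p from 0.0825 to 0.384) and without the control array of passage 13 (adjusted p from 0.0718 to 0.654). Leaving out the control array of passage 12, 19 or 20 also ended 1 or more of these calls (adjusted p from 0.101 to 0.510), as did the ASO_5+6 array of passage 12 for hypoxia and glycolysis (adjusted p = 0.207). At passages 12 and 13 alone cholesterol synthesis (0.19), ATF4 (0.093) and hypoxia and glycolysis genes (0.044) were not called (adjusted p from 0.473 to 0.844), and at passages 19 and 20 alone the ribosomal protein mean was 0.11.

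With ASO_7+8, 20 genes changed against control, 13 up and 7 down. All 20 had 1 sign at every passage, which their choice by the mean change over these passages favours. SERPINE2, a secreted protease inhibitor, rose by 2.23 log2 (SE 0.26, adjusted p = 5.24e-04, n = 4 per group, limma), from 8.99 ± 0.24 to 11.22 ± 0.61. KRTAP3-1 rose by 2.03, CYP24A1 by 1.79, EGR1, an immediate early transcription factor, by 1.76, TNS4 by 1.62, RAB3B by 1.57, CDKN1A by 1.56 and GLIPR1 by 1.55. EMC9 fell by 1.60, SNX24, a sorting nexin, by 1.52 (SE 0.18, adjusted p = 5.24e-04), GSTA1, a glutathione transferase, by 1.40, ODAM by 1.06, ZNF124 by 1.05 and MTARC1 by 1.00. With passage as a block, TNS4 and GLIPR1 no longer passed (adjusted p = 0.0565 and 0.0539). ZNFX1 was 0.55 above control (SE 0.24, adjusted p = 0.456). The count was 7 without the ASO_7+8 array of passage 19 and 37 without the ASO_3+4 array of passage 12, which enters through the shared spread. Of 15 genes named here as passing, 6 (SERPINE2, KRTAP3-1, CDKN1A, EMC9, SNX24 and KRT19) passed without any 1 of the 8 arrays.

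Among 25 p53 targets with ASO_7+8 (mean 0.28; adjusted camera p = 0.00608; with an estimated correlation adjusted p = 0.102), CDKN1A rose and 5 were higher when adjusted over the list alone. GADD45A, PLK2 and MDM2, the main p53 ubiquitin ligase, had values of 0.92, 0.66 and 0.50 that did not pass. The 23 mesenchymal and matrix genes had a mean of 0.28 (adjusted p = 0.00670; with an estimated correlation adjusted p = 0.102), none passed, and CCN1 and TAGLN had values of 1.20 and 1.15. Fry called these 2 lists and no other. G2/M genes had a mean of -0.34 (adjusted p = 9.06e-07; with an estimated correlation adjusted p = 0.541), with UBE2C and CENPF at -0.65 and -0.63, and G1/S genes a mean of -0.24 (adjusted p = 3.01e-04; with an estimated correlation adjusted p = 0.590). Ribosomal protein genes had a mean of -0.21 (adjusted p = 3.48e-05; with an estimated correlation adjusted p = 0.610). Oxidative phosphorylation genes had a mean of -0.20 (adjusted p = 0.00713) and fatty acid oxidation genes of -0.14 (adjusted p = 0.0492), both with adjusted p = 0.590 with an estimated correlation. At passages 19 and 20 alone, ribosomal protein and oxidative phosphorylation genes had means of 0.0088 and 0.043, the opposite direction, and fatty acid oxidation (-0.032, adjusted p = 0.755), G1/S (-0.15, adjusted p = 0.273) and mesenchymal genes (0.20, adjusted p = 0.273) were not called. At passages 12 and 13 alone the p53 targets had a mean of 0.15 and were not called (adjusted p = 0.473). Oxidative phosphorylation was not called without the control array of passage 12 (-0.085, adjusted p = 0.367) or 13 (-0.14, adjusted p = 0.0652). Fatty acid oxidation was not called without either of these, nor without the ASO_7+8 array of passage 12 or 19 (adjusted p from 0.0611 to 0.368). With quantile normalization neither list was called (adjusted p = 0.101 and 0.137), nor was fatty acid oxidation with bright genes only (adjusted p = 0.223). CSE1L, near ZFAS1, had a value of -0.69 (adjusted p = 0.118), and the ZFAS1 neighbourhood list was not called with any pair against control.

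**Figure D3:**
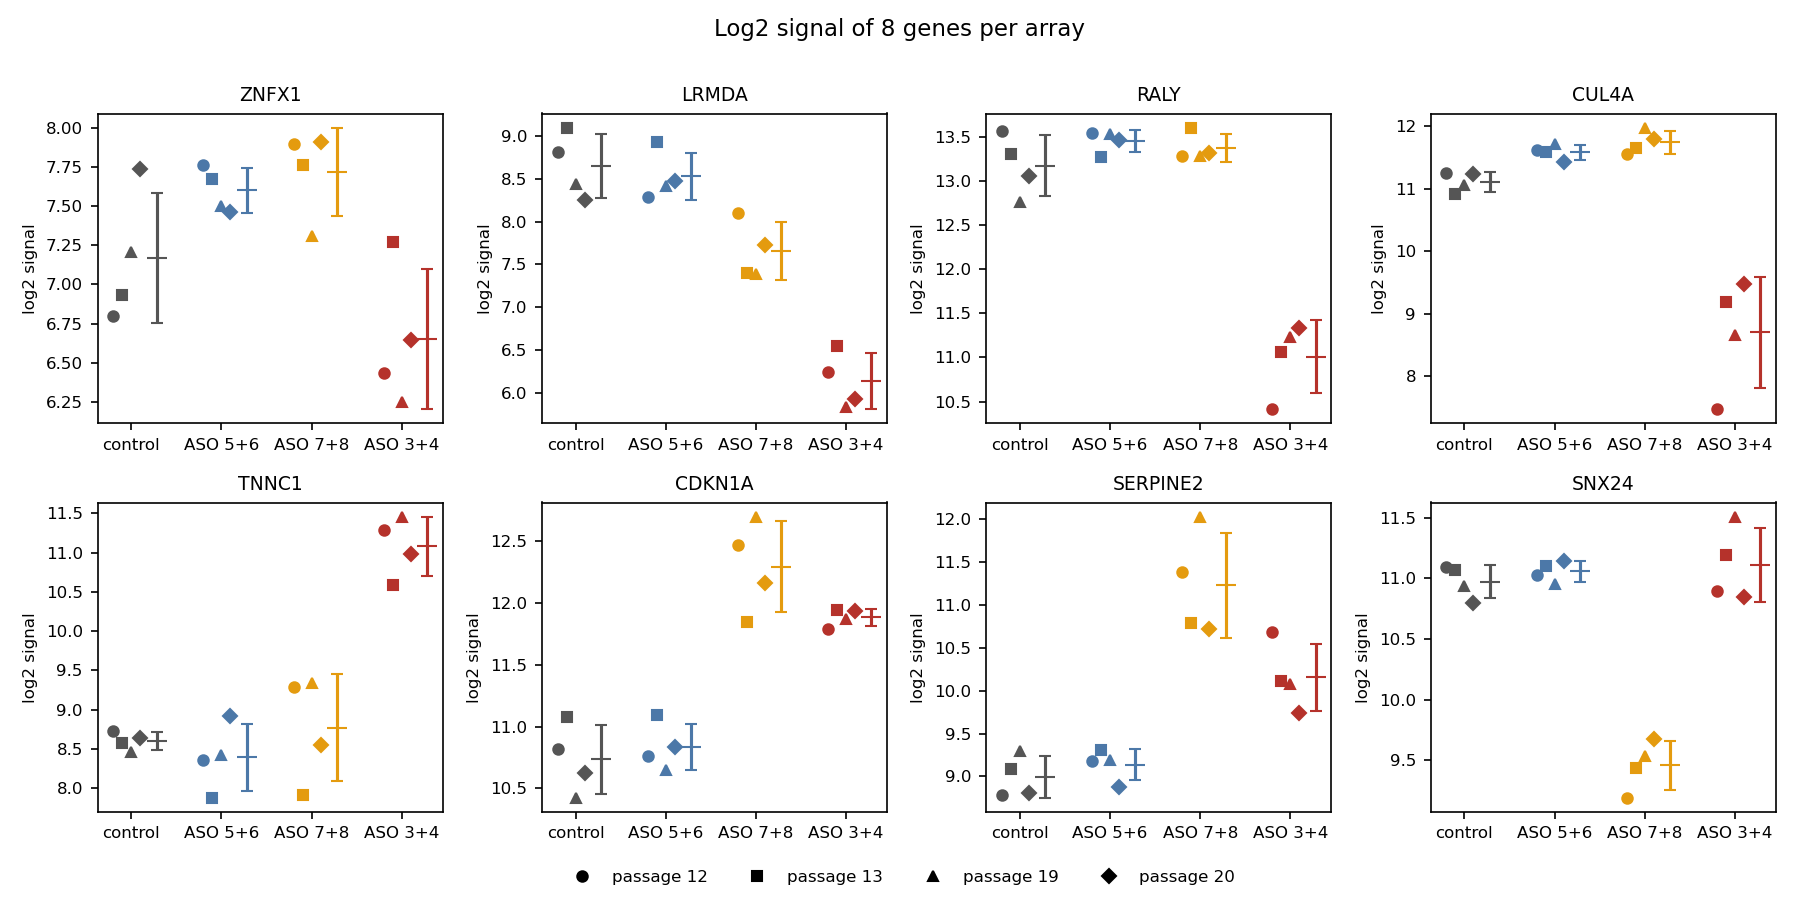
Log2 signal of 8 genes in each array, by group, with marker shape for passage and bars for the mean ± SD of 4 arrays. SNX24 was 9.46 ± 0.21 with ASO_7+8 and 10.97 ± 0.14 in control, and RALY was 11.01 ± 0.41 with ASO_3+4 and 13.17 ± 0.35 in control.

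Genes changed alike by every pair bear on the effect of the shared target. No gene passed in 1 direction with all 3 pairs in limma, a count fixed at 0 by the 0 genes of ASO_5+6, with or without the passage block. The 0 in each of 100 simulations of unchanged groups therefore tests nothing. At an unadjusted p under 0.05 the comparisons held 2215, 723 and 1713 genes. In the mean of the 3 pairs against control 5 genes passed, all named here after their values were seen. SUSD2 was higher by 0.95 (SE 0.15, adjusted p = 0.0394), KRTAP3-1 by 1.22, CDKN1A by 0.94 and KRT19, a keratin of simple epithelia, by 0.85, and LRMDA fell by 1.21. None of the 5 passed with ASO_5+6, where LRMDA had a value of -0.12, CDKN1A 0.10, KRTAP3-1 0.24, KRT19 0.29 and SUSD2 0.69. With the block, CDKN1A and KRT19 no longer passed (adjusted p = 0.0902 and 0.0556). Leaving out single arrays gave 0 to 7 genes, and 0 without any 1 of the 4 control arrays.

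With both ASO_3+4 and ASO_7+8, 6 genes rose, CDKN1A, CYP24A1, GLIPR1, KRT19, KRTAP3-1 and SERPINE2, with 0 in simulations of unchanged groups and 0.0742 expected of independent lists. The first value leaves out real effects and the second the shared controls, so neither gives the overlap of called genes without a shared effect. KRT19, chosen after its values were seen, rose by 1.05 and 1.22, and SERPINE2 and KRTAP3-1 rose by 1.16 and 1.39 with ASO_3+4. Across 10612 brighter genes, which are not independent replicates, the changes of these pairs correlated at 0.42, below the simulated median of 0.56 that shared controls give. The covariance, 0.0535, exceeded the simulated mean by 0.0112 and lay between the 5th and 95th percentiles of the simulated values (-0.00116 and 0.0985). With the controls split by passage, 2 arrays for each pair, the correlation was -0.07 or -0.39. The early and late controls themselves differed in 1490 genes, and this difference enters the 2 changes with opposite signs. It lowers every split correlation given here, so these values do not decide whether pairs share an effect. For ASO_3+4 and ASO_5+6 the correlation was -0.02 (simulated 0.55, covariance difference -0.0427, split -0.36 or -0.63), and for ASO_5+6 and ASO_7+8 it was 0.42 (simulated 0.54, covariance difference -0.00478, split -0.42 or -0.38).

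Differences between pairs were tested directly. Against ASO_5+6, ASO_3+4 had DCAKD lower, at -3.10 log2 (SE 0.68), CUL4A at -2.88 (SE 0.29, adjusted p = 2.16e-05), CDIN1 at -2.61 and SMYD3 at -2.47, and TNNC1 higher by 2.68. In all 522 genes differed, 161 higher and 361 lower (30.8% higher; 47.3% with quantile normalization). Of 30 G2/M genes 10 were lower and of 29 G1/S genes 9 (adjusted camera p = 5.72e-17 and 1.63e-12; with an estimated correlation adjusted p = 0.134 for each). KIF20A (-1.95), CDK1 (-1.48) and MCM5 (-1.75) among them were chosen after their values were seen. ZNFX1 was lower with ASO_3+4 than with ASO_5+6, at -0.95 (SE 0.24, adjusted p = 0.0336) and than with ASO_7+8, at -1.07 (adjusted p = 0.0358). Both calls depended on single arrays: the first was lost without any 1 of 7 of the 8 arrays compared, and the second without any 1 of 6 of 8. The range over all 18 alternatives was -1.16 to -0.82 (adjusted p up to 0.311) and -1.27 to -0.93 (adjusted p up to 0.404). DCAKD, KIF20A, CDK1 and MCM5 also lost their call without some 1 array. The count of 522 was 149 without the ASO_5+6 array of passage 19, 237 without the ASO_3+4 array of passage 12 and 1014 without that of passage 13.

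Against ASO_7+8, ASO_3+4 differed in 138 genes, 55 higher and 83 lower. CUL4A was lower, at -3.04 log2 (SE 0.29, adjusted p = 1.73e-05), RALY at -2.36, MYH9 at -2.22 and CDIN1 at -2.22, and TNNC1 was higher by 2.30. CDIN1 no longer passed with the passage block (adjusted p = 0.0523) or without some 1 array. The 138 genes were 55 without the ASO_7+8 array of passage 19. Between ASO_5+6 and ASO_7+8 there were 9 genes, 2 higher and 7 lower with ASO_5+6. SERPINE2 was lower, at -2.09 (SE 0.26, adjusted p = 0.00105), KRTAP3-1 at -1.80, GLIPR1 at -1.66, AKAP12, a kinase scaffold, at -1.51 and CDKN1A at -1.46, while SNX24 was higher by 1.60. The GLIPR1 call was lost without any 1 of 7 of the 8 arrays.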

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

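Tests chosen only after the result was seen were the swap of labels, the passage effect, the spread and background of the arrays, the counts within passages, and the test of shared controls. Of 251 sets of 4 arrays, 13 held an array far from the other 3 (5.18%), and chance alone gives about 1 in 20. With ASO_3+4, SFN was 11.64 at passage 13 (others from 12.19), CD68 11.80 at passage 13, SAMD9 4.89 at passage 13 and PSKH1 5.05 at passage 12. With ASO_7+8, RALY was 13.60 at passage 13, and GADD45A (10.95), CSE1L (15.11) and SUSD2 (8.85) stood apart at passage 12. MSMO1 was 16.69 with ASO_5+6 at passage 19, and MLF2 was 10.72 in the control of passage 12. The interferon list mean was 6.18 with ASO_5+6 at passage 13, and the hypoxia and glycolysis list mean 10.94 in the control of passage 12. The median gene signal was 6.51 in the ASO_5+6 array of passage 19. Among rows without a gene name, 5 passed for ASO_3+4 and 1 for ASO_7+8 against control, 23 between ASO_3+4 and ASO_5+6, 8 between ASO_3+4 and ASO_7+8, and 1 between ASO_5+6 and ASO_7+8.

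The effect of ASO_3+4 differed between passages 12 and 13 and passages 19 and 20 in 2219 genes by an interaction test in limma. The late minus early difference in the change was -1.75 for GLIPR1, 1.27 for AKR1B10, -1.83 for DLGAP5 and -1.92 for LGR5. The control arrays alone differed between these passages in 1490 genes and the ASO_3+4 arrays alone in 40. At an unadjusted limma p under 0.05 these counts were 3960 and 2681, against 884.35 by chance, so ASO_3+4 arrays shifted as well. For a swap of ASO_3+4 and control labels at passages 19 and 20, values go both ways. Against it speak 50 genes that set ASO_3+4 apart from the other pairs at passages 12 and 13. Their median shift was at least 0.92 in its later arrays, against at most 0.27 in the later controls. With it, the later ASO_3+4 arrays correlated at 0.989 to 0.990 with the earlier controls, against 0.976 to 0.987 with the earlier ASO_3+4 arrays. The low end came from the low-spread array of passage 12, and values with passage 13 were 0.984 and 0.987. Arrays of ASO_5+6 and ASO_7+8 reached 0.991 with the control of passage 12 and 0.988 with that of passage 13. Such a correlation alone therefore does not mark a control array. The grouping a swap would give also called 2022 genes, against 198 as labelled, so a swap stays open. A passage effect common to all groups is argued against by the correlation across genes of late minus early changes, -0.61 between ASO_3+4 and control. Between ASO_7+8 and control that correlation was 0.51, and none of its 16 array combinations was negative, so a passage shift shared by these 2 groups stays open. Late controls had a spread over genes of 3.18 and 3.16, between the early values of 3.19 and 3.14 (mean difference 0.00677). This argues weakly, with 2 arrays on each side, against the spread as a cause of the control shift. Over the 16 arrays, however, the first principal component followed the spread (r = 0.612). For the ASO_3+4 arrays the spread was not tested as a cause. Background is argued against for the ASO_3+4 arrays, whose late and early levels overlapped (difference -0.0184 log2). It stays open for the controls (-0.192), since ASO_5+6 (0.0672) and ASO_7+8 (-0.103) lay apart as well and 0 genes differed in them, as does a response to the oligonucleotide that depends on passage, which is untested.

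Of the 35 splits of the 8 arrays, 4 gave as many genes as ASO_3+4 against control (198), and the highest other gave 2022, so chance cannot be excluded for this count. That split sets the ASO_3+4 arrays of passages 12 and 13 with the controls of passages 19 and 20 against the rest. It is the grouping that opposite shifts of the 2 groups between passages, or swapped labels, would give. The split of passages 12 and 13 against passages 19 and 20 gave 0 genes. Within passages the counts were 870 and 1651, and of 284 genes called in both, 233 had opposite signs. Among the 8 splits that part all passage pairs, 3 gave as many. The list count of 10 was met by 6 of 35 splits (highest other 11). Without the low-spread array of passage 12 the count was 123, between the bounds that would have decided for or against that array as the source. Whether the split of the controls hides changes of ASO_5+6 stays open. Within either pair of passages, with 2 arrays per group, ASO_5+6 changed 0 genes, but its early and late changes correlated at -0.28 across genes. The difference between them held 2235 genes at an unadjusted p under 0.05, against 884.35 by chance.

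For ASO_7+8 against control, 1 of 35 splits, the real one, gave 20 genes (highest other 7), and 2 of 35 gave its 7 lists (highest other 8). Between pairs, 1 of 35 splits gave as many genes in each case, with 522, 138 and 9 genes and 0, 3 and 0 as the highest other. A share of 1 in 35 (0.0286) is the smallest this test can give, and it is not adjusted over the comparisons. The test also exchanges arrays without regard to passage, which they share across groups. The labelled grouping stood out for these 4 gene counts, but chance is not excluded. Among the 8 splits that part every passage the real one alone gave as many in each of the 4 (highest other 0), but 8 are too few for a share under 0.05. For ASO_5+6 against control all 35 splits gave 0 genes, which any split reaches, and 7 of 35 gave its 4 lists (highest other 5). Of 100 drawn splits of all 16 arrays, 1 gave the 5 genes of the mean of the pairs (highest other 1), and 100 gave the 0 genes changed alike (highest other 0), which tests nothing.

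The rise of 6 genes with both ASO_3+4 and ASO_7+8 was set against low control arrays as its source. All 6 were higher than with ASO_5+6 for both pairs, and 4 of them (CDKN1A, GLIPR1, KRTAP3-1 and SERPINE2) passed in both comparisons. With ASO_5+6 the 6 genes lay from -0.10 (GLIPR1) to 0.29 log2 (KRT19) relative to control. This argues against the shared control arrays, but only weakly. The genes were chosen for high values in these same ASO arrays, and ASO_5+6 is again 1 baseline for both comparisons. Leaving out single ASO arrays gave 1 to 4 such genes, fewer than 3 in 5 of 12 cases, and of the 6 genes CDKN1A alone passed in all 12, so for the others this argument rests on single arrays. That these genes respond to what the 2 pairs have in common is a hypothesis, found and tested on the same arrays.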

How the results depend on the processing

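Array weights, all rows and the fit by passages were chosen after seeing the data. So were counts without the ASO_3+4 array of passage 12, for comparisons that do not hold ASO_3+4. The cause of the moves below was not tested, and fewer arrays or genes enter some of the fits. Of 73 called gene results named in the text none changed sign, and 11 kept their call in every alternative, among them LRMDA, CUL4A, RALY, TNNC1, RCL1, SFN, IMMP2L, NKD1, GLIPR1 and MMP3 with ASO_3+4. The largest rises and falls against control were named for having 1 sign at all 4 passages. Early or late passages alone therefore could not change their sign, and this count is partly fixed by the naming rule. ZFAS1 changes have no value here. With the replicate block (passage) the counts were 227, 0 and 18 for ASO_3+4, ASO_5+6 and ASO_7+8 against control, 633, 140 and 12 between pairs, 7 for the mean and 0 alike, and 5 of 102 named gene results lost their call (TNS4 and GLIPR1 with ASO_7+8, CDKN1A and KRT19 in the mean, and CDIN1). Lists with estimated correlation were 0, 0 and 0 for the 3 pairs, and with fry 0 for ASO_5+6 and 2 for ASO_7+8. ASO_5+6 lists were 1 with quantile normalization, 1 with bright genes only and 1 at early passages. The mean of the pairs gave 1 gene when centred (0 higher and 1 lower, against 4 and 1), 8 with bright genes, 2 with array weights and 0 with all rows. Fits of only the compared groups gave 34 genes for ASO_3+4, 7 for ASO_7+8 and 58 for ASO_3+4 against ASO_7+8. They gave 35 for ASO_5+6 against ASO_7+8 and 587 for ASO_3+4 against ASO_5+6. These lay above the main counts of 9 and 522, so fewer arrays in a fit did not always lower a count. Early passages alone gave 120 genes for ASO_3+4, 0 for ASO_7+8, 0 for the mean, and 3, 1 and 0 between pairs. Late passages alone gave 2187 for ASO_3+4, 0 for ASO_7+8, 437 for the mean, 591 for ASO_3+4 against ASO_7+8, 0 for ASO_5+6 against ASO_7+8, and 6, 7 and 2 lists. There, fatty acid oxidation (0.075) and ribosome biogenesis (0.032) reversed with ASO_3+4, ribosomal proteins with ASO_5+6 (0.11), and ribosomal proteins (0.0088) and oxidative phosphorylation (0.043) with ASO_7+8. From early to late passages, ribosomal protein means moved by -0.53 in control, -0.058 in ASO_5+6 and -0.10 in ASO_7+8. Oxidative phosphorylation means moved by -0.56 in control and -0.065 in ASO_7+8. The reversals of these lists with ASO_5+6 and ASO_7+8 thus lay mostly in the control arrays. Array weights gave 128 genes for ASO_3+4 and 1137, 225 and 158 between pairs. Within passages 12 and 13, ASO_3+4 changed 870 and ASO_7+8 11 genes, and within 19 and 20 1651 and 7. Leaving out 1 array gave 113 to 321 genes for ASO_3+4, 0 to 1 for ASO_5+6, 7 to 37 for ASO_7+8, 149 to 1014, 55 to 193 and 5 to 14 between pairs, 0 to 7 for the mean and 0 alike, and 7 to 12, 0 to 5 and 5 to 9 lists.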

Other observations

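The list comparisons between passages and the relations with the first principal component were chosen after the result was seen. Between pairs of ASOs, camera at its preset correlation called 13 lists for ASO_3+4 against ASO_5+6, 7 for ASO_3+4 against ASO_7+8 and 9 for ASO_5+6 against ASO_7+8. Fry called 13, 1 and 0, and an estimated correlation left 0 in each. Against ASO_7+8, ASO_5+6 had higher means for G2/M genes (0.46 log2), G1/S genes (0.40) and cholesterol synthesis genes (0.35), with adjusted camera p of 4.41e-11, 2.28e-08 and 2.17e-05. No member of the 3 lists passed over all genes, and with an estimated correlation each list had an adjusted p = 0.170. Against ASO_7+8, ASO_3+4 had a higher mean for NRF2 and oxidative stress genes (0.41, 2 of 23 passed up; adjusted p = 7.74e-06, and adjusted p = 0.207 with an estimated correlation), the 1 list fry called (adjusted p = 0.0150).

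The control arrays themselves changed with passage. From passages 12 and 13 to passages 19 and 20, ribosomal protein genes had a mean of -0.53 log2 in CTLASO and 8 of 39 fell, oxidative phosphorylation genes had a mean of -0.56 with 9 of 27 down and 1 up, and G2/M genes had a mean of 0.46 with 6 of 30 up. Camera called these lists at adjusted p of 5.54e-09, 5.48e-05 and 0.0115, and with an estimated correlation their adjusted p were 0.673, 0.572 and 0.779. In ASO_3+4, ribosomal protein and oxidative phosphorylation genes had means of 0.29 and 0.39 between these passages, with no member passing (adjusted camera p = 8.42e-04 for each; with an estimated correlation adjusted p = 0.621 and 0.593). In ASO_5+6 and ASO_7+8, 0 genes differed between these passages in limma, with 282 and 879 at an unadjusted p under 0.05.

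Over the 16 arrays, the first principal component followed the spread over genes (r = 0.612, permutation p = 0.00826; rho = 0.668, permutation p = 0.00622; r = 0.588 without the 2 farthest arrays) and the negative control level (r = -0.544, permutation p = 0.0290; rho = -0.556, permutation p = 0.0284; r = -0.447 without the 2 farthest). Adjusted over these 2 relations, the p of r were 0.0165 and 0.0290. The permutations exchanged all 16 arrays without regard to group or passage, so these p-values ignore that structure.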
